A study of Mus musculus with 47 samples.

How the data were processed

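The values used were expected counts per gene, as the notes of the submitters and the deposited tables give them, in 1 table of O4+ cells and 1 table of bulk tissue. According to those notes STAR 2.7.10 and RSEM 1.3.3 were used with the mouse assembly GRCm39. The notes do not say which settings, annotation or filters applied, so these are not given in the sources used here. Per the labels, the O4+ libraries were made with a SMART-Seq Stranded kit and sequenced on an Illumina NextSeq, and the bulk libraries with a SureSelect Strand-Specific kit on an Illumina NovaSeq. Expected counts were rounded to whole numbers before every fit. The tables hold 40760 genes, and library totals had medians of 14 M (mega) counts in O4+ cells, 18.8 M in spinal cord and 16.7 M in lymph node.

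Groups came from the labels only. All 47 columns were matched to samples by the labels, and 1 of them, a nestin cKO lymph node library, only to its group, because its column carries the number 3 while the titles of that group carry 1 and 2. The column of the lymph node cspg4 control carries a 2 where its title has no number, and block fits of bulk tissue used numbers of titles only. The bulk cord libraries comprised 6 EAE controls (2 of the cspg4 line, 1 of cx3cr1, 2 of nestin and 1 with no line given), 3 EAE cKO libraries each of the cspg4, pdgfra, cx3cr1 and nestin lines, and 1 control and 1 cx3cr1 cKO library without EAE. The lymph node libraries comprised 4 EAE controls, 2 cspg4, 3 pdgfra, 3 cx3cr1 and 2 nestin cKO libraries and 1 control without EAE. EAE controls of all lines were pooled because no EAE control is labelled pdgfra. The O4+ libraries comprised 5 of brain and 5 of cord from the cspg4 and pdgfra lines, 3 cKO and 2 control in each tissue, and 2 of brain from the cx3cr1 line, which were reported as values because each stands alone.

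Counts were tested in R 4.3.3 with edgeR 4.0.16, by quasi-likelihood F tests (two-sided) after TMM normalization and filterByExpr (min.count 10, min.total.count 15), with a Benjamini-Hochberg adjusted p under 0.05 as the call. One fit held all bulk cord libraries, one all lymph node libraries, one the EAE libraries of both tissues and one each the O4+ sets, with 1 mean per arm. The common biological coefficient of variation was 0.248 in cord, 0.197 in lymph node, 0.239 in brain O4+ cells and 0.175 in cord O4+ cells. Fold changes are coefficients of the edgeR fit, with an SE taken from the coefficient and its F statistic, and log2 CPM values used a prior count of 2. For genes without counts in the second group a floor fold was computed by giving that group 3 counts in all. The targeted gene was compared by two-sided exact permutation of CPM, with adjustment over the 8 tests.

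The lists tested numbered 42, of which 1 had no member in the tables. They cover antigen presentation, proteasome parts, immune and neural cell types, stress responses, lipid synthesis and positional genes, and were written from general knowledge before the data were examined. They were tested with camera in limma 3.58.1 (two-sided, preset correlation 0.01, BH over the lists of a comparison, at least 3 tested members), and again with an estimated correlation. Of all lists called with the preset correlation, 3 kept the call with an estimated correlation, all between cord and brain O4+ cells. The comparisons, tests, lists, named genes and other settings tried were fixed before the data were examined.

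Named genes followed a rule. In each comparison it names Ecpas, and up to 8 higher and 8 lower genes with the largest absolute log2 fold change among those called, with an average log2 CPM of at least 1 and every library of the first group on the same side of the mean of the second. Predicted genes, immunoglobulin and T-cell receptor segments, mitochondrial, ribosomal and microRNA genes and sex-linked marker genes were passed over. It adds up to 4 members of each called list with the smallest p in the direction of the list. The genes H2-K1, H2-Ab1, Cd74, Psmb8, Psmb9, Mog, Mbp, Foxp3, Ifng, Il17a and Cd4, and 1 further gene that is not reported here, were always included for cKO against control in cord and in O4+ cells. Where fewer than 3 genes passed in a direction, the 3 with the smallest p were given as values. The text names a part of the genes that the rule gives, and genes outside it are marked as chosen after their values were seen.

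The other settings fixed beforehand were DESeq2 1.42.0 with its own size factors, RLE factors in edgeR, no filter on low counts, each library left out in turn, the number in the labels as a block, only the arms compared, log2 CPM of Xist as a covariate, controls of the own line or of the cspg4 line only, line as a covariate, the cx3cr1 brain libraries as further controls, summed brain and cord counts per label number, and control libraries alone for EAE. Fits that use the blocks of column numbers, and the region fit without a pair of cspg4 cKO libraries rich in Pdgfra, were chosen after seeing the data.

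The pipeline was tested on simulated data drawn with the means, totals and dispersions of the libraries, with 100 genes changed by each fold. At a 2-fold change it recovered 84% of them in cord for oligodendroglial cKO, 88% in lymph node, 32% in brain O4+ cells, 52% in cord O4+ cells and 25% for EAE in lymph node, and at a 4-fold change 98%, 99%, 77%, 88% and 85%. Libraries were checked for duplicates, and the lowest chi-square per degree of freedom among the 24 pairs of replicates compared was 15.6. Groups of 3 or more libraries were also regrouped at random or in full, up to 100 splits per comparison. Exon use and sequence variants were not analysed here, because the tables hold counts per gene, and functional terms beyond the lists were not analysed here.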

Results

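The series addresses whether loss of Ecm29 in oligodendroglia changes the inflammatory response in mice with experimental autoimmune encephalomyelitis (EAE), an immune attack on myelin of the central nervous system. Ecm29, encoded by Ecpas, is an adaptor that binds the proteasome. Conditional knockout (cKO) mice of the cspg4, pdgfra, cx3cr1 and nestin lines and controls gave 20 spinal cord libraries, 15 lymph node libraries and 12 libraries of sorted O4+ cells. The cspg4 and pdgfra lines are together called oligodendroglial here. Library totals, in units of 1 M (mega) counts, were 13.2 to 34.5 in cord, 14.1 to 20.6 in lymph node and 9.03 to 15.9 in O4+ cells.

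Ecpas did not differ between cKO libraries and controls at an adjusted p under 0.05 in any sample set, by two-sided exact permutation tests of CPM, the counts scaled to a library total of 1 M (mega). In EAE cord it stood at 150 ± 11.4 CPM (mean ± SD) in 6 oligodendroglial cKO libraries, 154 ± 7.82 in 3 cx3cr1 cKO libraries and 154 ± 12.8 in 3 nestin cKO libraries, against 139 ± 6.38 in 6 controls. The exact p values of 0.0476, 0.0238 and 0.0357 each became 0.127 after adjustment over the 8 tests. In lymph node the oligodendroglial cKO mean was 174 ± 17.9 CPM (n = 5), the cx3cr1 cKO mean 159 ± 12 (n = 3) and the nestin cKO mean 147 ± 19 (n = 2), against 161 ± 6.95 in 4 controls (exact p = 0.246, 0.829 and 0.267, adjusted 0.427, 0.829 and 0.427). The smallest exact p that the nestin groups could reach was 0.0667, so that test could not have passed. In O4+ cells Ecpas stood at 141 ± 14.8 CPM in 3 cKO and 131 ± 3.19 in 2 control brain libraries, and at 126 ± 13.6 and 124 ± 0.424 CPM in cord (exact p = 0.5 and 0.7, adjusted 0.667 and 0.8, smallest possible 0.1). The ratios of cKO to control means spanned 0.917 in nestin nodes to 1.10 in cx3cr1 and nestin cords. Counts per gene do not show whether single exons were deleted, and whole cord and node hold many cells that a line does not target.

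In EAE cord the oligodendroglial cKO libraries (n = 6, controls n = 6) carried more neutrophil transcripts. All 12 neutrophil genes lay higher, with a median log2 fold change of 0.84 (camera adjusted p = 1.26e-06, 0.856 with an estimated correlation). S100a8, which encodes a calprotectin subunit of neutrophils and monocytes, lay higher by 1.12 log2 (SE 0.37), at 50.2 ± 18.9 against 22.9 ± 9.43 CPM, with 6 of 6 cKO libraries above the control mean. Itgb2l and Retnlg, both expressed in neutrophils, lay higher by 1.65 (SE 0.33) and 1.17 log2 (SE 0.35). Numbers in the column names put the cord libraries into a high and a low block. Within the high block, which holds all 3 cspg4 cKO, 2 pdgfra cKO and 2 EAE control libraries, the neutrophil median was 0.7 (adjusted p = 1.05e-08). In the low block the only oligodendroglial library was from the pdgfra line, with a neutrophil median of 0.55 over 4 controls and no replicate to test it.

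The 14 genes of the 20S proteasome core also all lay higher in these cKO cords, by a median of 0.22 log2 (adjusted p = 0.000213, 0.856 with an estimated correlation). Psmb5, a catalytic subunit, lay higher by 0.24 log2 (SE 0.098), at 64.6 ± 7.52 against 54.3 ± 7.25 CPM, and within the high block the list median was 0.04 (adjusted p = 0.282). All 18 genes of cholesterol synthesis lay lower, by a median of −0.39 log2 (adjusted p = 0.00131, 0.856 with an estimated correlation, −0.22 and 0.000121 within the high block), and by −0.2 without control 1, the control with no line given. All 15 neuronal genes lay lower, with a median of −0.29 (adjusted p = 0.00131, 0.856 with an estimated correlation, −0.04 and 0.19 within the high block, −0.13 without control 1), including the heavy neurofilament Nefh at −0.50 (SE 0.20). The 12 endothelial genes lay lower by a median of −0.53 log2 (adjusted p = 4.47e-06, 0.856 with an estimated correlation), with the vascular receptor Tek at −0.96 (SE 0.23), but the median was 0 within the high block (adjusted p = 0.72) and −0.08 (adjusted p = 0.688) against cspg4 controls alone.

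**Figure D1:**
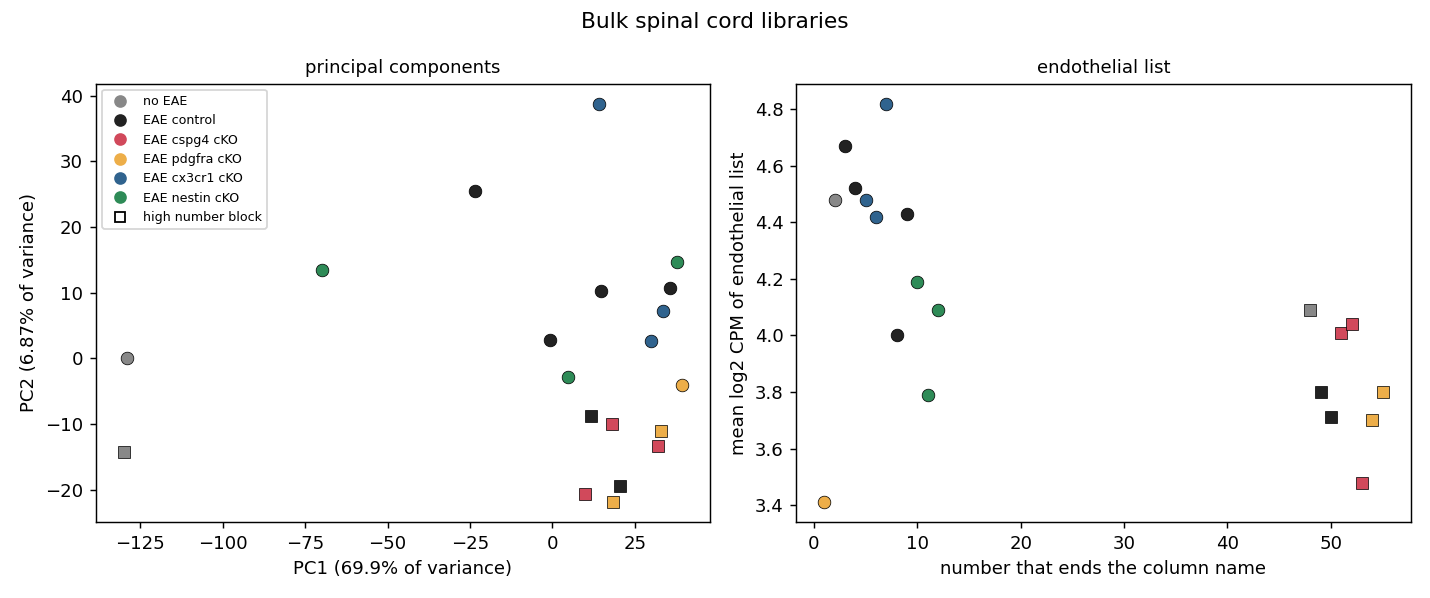
First and second principal components of bulk spinal cord libraries (axes, 69.9% and 6.87% of variance), and the mean log2 CPM of the endothelial list (vertical) by column number (horizontal). Points are libraries, coloured by arm, with squares for the high block. Endothelial means were 3.76 in controls of the high block and 4.4 in those of the low block.

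By gene, edgeR called 0 of 18704 in this comparison. The count at unadjusted p under 0.05 was 1826, against 935 expected by chance, and DESeq2 called 14 genes. The 3 smallest edgeR p values with higher counts in cKO belonged to Itgb2l, Slc25a34 and Pou3f1, and those with lower counts to Col11a1, Dnah10 and Pip5kl1. Itgb2l, at 4.17 ± 0.612 against 1.32 ± 0.401 CPM, had an adjusted p of 0.503 in edgeR and 0.00367 in DESeq2. Col11a1, which encodes a fibrillar collagen chain, had a log2 fold change of −1.24 (SE 0.25, 15.4 ± 2.31 against 36.3 ± 17 CPM, adjusted p = 0.503 in edgeR and 0.00645 in DESeq2). Adjusted over the list alone, 2 endothelial genes and 1 neuronal gene were called.

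The antigen-presentation, T-cell and myelin genes fixed in advance gave 0 calls of 12, with edgeR adjusted p from 0.645 to 0.965. H2-Ab1, an MHC class II chain, lay higher by 0.56 log2 (SE 0.59, 913 ± 341 against 612 ± 499 CPM) and H2-K1, of MHC class I, by 0.39 (SE 0.42). The interferon-induced proteasome subunits Psmb8 and Psmb9 lay higher by 0.35 and 0.28 log2 (SE 0.35 each), and Foxp3, which marks regulatory T cells, lay at −0.26 (SE 0.40). The myelin genes Mbp and Mog lay at −0.18 (SE 0.21) and −0.11 log2 (SE 0.17). As a list, T-cell genes had a median of 0.06 (adjusted p = 0.393), regulatory T-cell genes 0 (adjusted p = 0.873) and the immunoproteasome 0.26 (adjusted p = 0.191).

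**Figure D2:**
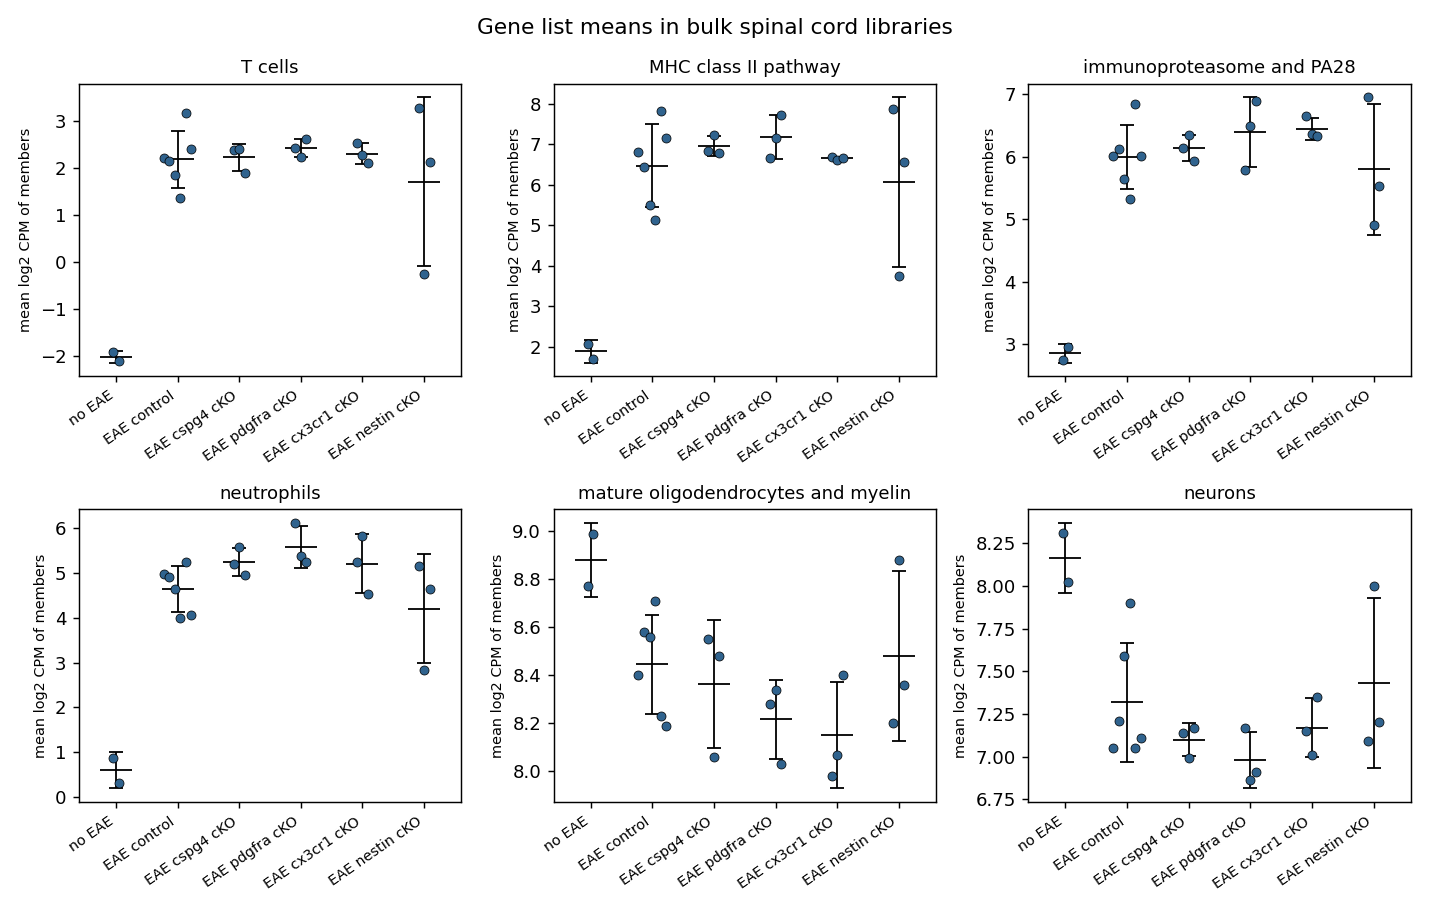
Mean log2 CPM of 6 gene lists (vertical axes) in spinal cord by arm (horizontal axis), with points for libraries and bars for mean ± SD. The T-cell list lay far above the 2 cords without EAE in every EAE arm, and the neutrophil list lay higher in the cKO arms of the cspg4 and pdgfra lines than in EAE controls, by medians of 0.6 and 1.11 log2.

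Both oligodendroglial lines showed the neutrophil difference, which was not particular to them. The median was 0.6 log2 in cspg4 cKO cords (n = 3 against 6 controls, adjusted p = 0.000134, 0.966 with an estimated correlation) and 1.11 in pdgfra cKO cords (n = 3, adjusted p = 2.85e-06, 0.746 with an estimated correlation, 4 genes adjusted over the list alone, median 0.5 without pdgfra cKO 1). S100a8 lay higher by 0.95 log2 (SE 0.44) in cspg4 cKO cords, and the 8 red blood cell genes lay higher there by a median of 1.23 (adjusted p = 1.4e-06, 0.966 with an estimated correlation, 0.72 without cspg4 cKO 2), with beta-globin Hbb-bt at 51.3 ± 25.5 against 16.7 ± 14.5 CPM. With the column-number block as a term these cspg4 medians were 0.24 (adjusted p = 0.0369) and 0.97 (1.31e-06). Sex is confounded in part with the cspg4 comparison. All 3 cspg4 cKO cords had the Y-linked gene Ddx3y (106.7 to 134.2 CPM). Of the controls, cspg4 control 1, nestin control 1 and control 1 had it (73.12 to 113 CPM), and the others had 0 CPM. Cxcl13, a B-cell chemokine, lay higher in cspg4 cKO by 2.82 log2 (SE 0.80), at 74.3 ± 83 against 10.5 ± 5.4 CPM. In cx3cr1 cKO cords the neutrophil median was 0.55 (n = 3, adjusted p = 0.000133, 0.723 with an estimated correlation, but 0.13 and 0.183 without cx3cr1 cKO 2), with Itgb2l higher by 1.8 log2 (SE 0.37, adjusted p = 0.875 in edgeR and 0.0186 in DESeq2). Oligodendroglial against cx3cr1 cKO had a neutrophil median of 0.13 (adjusted p = 0.565). Ecpas lay at 0.04 log2 (SE 0.088, edgeR adjusted p = 0.963) in cspg4 and 0.15 (SE 0.087, 0.467) in pdgfra cKO cords.

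The pdgfra cKO cords also carried higher 20S core genes (median 0.25, adjusted p = 6.44e-05, 0.814 with an estimated correlation, but 0.09 and 0.0843 within the high block), with Psmb5 at 71.3 ± 2.32 against 54.3 ± 7.25 CPM. Trib3, a pseudokinase induced by the integrated stress response, lay higher by 1.99 log2 (SE 0.42, 4.15 ± 2.2 against 1.03 ± 0.412 CPM), and the stress-response list by a median of 0.27 (adjusted p = 0.000259, 0.65 with an estimated correlation). The cholesterol list lay at −0.56 (adjusted p = 0.000274, 0.814 with an estimated correlation, −0.37 without control 1) and the endothelial list at −0.59 (adjusted p = 7.96e-06, 0.746 with an estimated correlation), with Tek at −1.24 (SE 0.30). Within the high block, which holds 2 of the 3 pdgfra cKO cords, the endothelial median was −0.07 (adjusted p = 0.685). EdgeR called 0 genes in either line, with 777 at unadjusted p under 0.05 for cspg4 and 2083 for pdgfra, and DESeq2 called 1 and 12. In the direct test of pdgfra against cspg4 cKO cords edgeR called 0 genes (728 at unadjusted p under 0.05, DESeq2 0). Sex is confounded in part with that test, since all cspg4 cKO cords had Ddx3y while pdgfra cKO 2 and 3 had 0 CPM of it.

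The cx3cr1 line targets microglia and other myeloid cells. In its 3 EAE cords interferon-stimulated genes lay higher than in 6 controls, in 23 of 24 members, by a median of 0.56 log2 (adjusted p = 1.59e-10, 0.723 with an estimated correlation), and by 0.43 (adjusted p = 2.17e-07) with the column-number block as a term. Irgm1, an interferon-induced GTPase, stood at 544 ± 32.7 against 303 ± 102 CPM, and Irf7, which amplifies type I interferon, at 136 ± 36.4 against 80.9 ± 25.9. Monocyte and macrophage genes lay higher by 0.6 (adjusted p = 5.83e-07, 0.723 with an estimated correlation), with Arg1 at 977 ± 360 against 264 ± 143 CPM. Immediate early genes lay higher by 0.46 (adjusted p = 8.88e-09, 0.644 with an estimated correlation) and reactive astrocyte genes by 0.61 (adjusted p = 2.28e-06, 0.723 with an estimated correlation), among them Timp1 by 0.89 log2 (SE 0.47). Myelin genes lay lower in 20 of 22 members, by a median of −0.34 (adjusted p = 1.39e-05, 0.723 with an estimated correlation), with Mbp at 1.06e+04 ± 1.92e+03 against 1.64e+04 ± 3.54e+03 CPM. Ecpas lay at 0.13 log2 (SE 0.087, adjusted p = 0.875). Sex is confounded in part here too, since the 3 cx3cr1 cKO cords had 0 CPM of Ddx3y. Of the controls, cspg4 control 1, nestin control 1 and control 1 had 73.12 to 113 CPM of it. EdgeR called 0 genes (948 at unadjusted p under 0.05), DESeq2 called 5, and the 12 fixed genes gave 0 calls.

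In the direct test of oligodendroglial against cx3cr1 cKO cords (n = 6 and 3), all 12 endothelial genes lay lower in oligodendroglial cKO, by a median of −0.81 log2 (adjusted p = 9.77e-12, 0.277 with an estimated correlation, 10 genes adjusted over the list alone). Pecam1, an endothelial junction protein, stood at 14.4 ± 3.18 against 31.8 ± 8.85 CPM. Interferon-stimulated genes lay lower in 23 of 24 members by a median of −0.55 (adjusted p = 2.96e-07, 0.979 with an estimated correlation), with the T-cell chemokine Cxcl10 at 75 ± 36.3 against 179 ± 12.1 CPM. EdgeR called 1 gene, LOC118567825, at −3.78 log2 (SE 0.53, adjusted p = 0.0382), chosen for naming after its values were seen. Leaving out cx3cr1 cKO 2 gave 4 calls, and leaving out any of the other 8 libraries gave 0. DESeq2 called 222 genes, and Ecpas lay at −0.04 log2 (SE 0.088). This contrast is confounded with the column numbers, since 5 of 6 oligodendroglial and 0 of 3 cx3cr1 cKO cords lay in the high block. It is also confounded in part with sex. All cx3cr1 cKO cords, and pdgfra cKO 2 and 3, had counts of Xist (310.2 to 963.1 CPM) and 0 CPM of the Y-linked gene Ddx3y. All cspg4 cKO cords and pdgfra cKO 1 had Ddx3y (99.87 to 134.2 CPM) and almost no Xist. With Xist as a covariate edgeR called 0 genes. With the block as a term the endothelial median was −0.46 (adjusted p = 6.23e-09), the interferon median −0.25 (adjusted p = 0.00124) and the edgeR adjusted p of LOC118567825 was 1.

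Nestin cKO cords (n = 3 against 6 controls) had 4 genes called by edgeR, all higher, and 13 by DESeq2. H2-Bl, an MHC class I-like gene, rose by 3.07 log2 (SE 0.3, adjusted p = 0.000236), and Glo1, a glyoxalase that detoxifies methylglyoxal, rose 1.79-fold from 104 ± 9.18 to 186 ± 28.8 CPM (SE 0.11 log2, adjusted p = 0.00611). Hmga1b and Atp6v0c-ps2 rose by 3.93 (SE 0.56) and 4.56 log2 (SE 0.65, adjusted p = 0.0111 each), but nestin cKO 3 stood at 0.478 and 0.584 CPM, near the controls. H2-Bl and Hmga1b were chosen for naming after their values were seen. The count was 1 without nestin cKO 1 or 2, 2 without cx3cr1 control 1 and 7 without nestin cKO 3. The Glo1 adjusted p was 0.0505 without nestin cKO 1 and 0.0579 without nestin cKO 2. That of Hmga1b and Atp6v0c-ps2 was 0.0505 to 0.0579 without nestin cKO 1, nestin cKO 2 or cx3cr1 control 1, and 0.0528 for Atp6v0c-ps2 without nestin control 1. Against the 2 nestin-line controls alone 0 genes were called in edgeR, with Glo1 at 0.96 log2 (adjusted p = 0.177) and H2-Bl at 3.3 (adjusted p = 0.145), and with only the arms compared Glo1 had 0.85 log2 (adjusted p = 0.264). Glo1 and H2-Bl lie on chromosome 17, which held 15 of the 49 placed genes among the 50 of smallest p (2.4 expected). A variant there in the mice cannot be told apart from deletion of Ecm29. Proliferation genes lay lower in 16 of 16 members by a median of −0.47 (adjusted p = 6e-09, 0.824 with an estimated correlation), but at −0.14 (adjusted p = 0.0948) without nestin cKO 2, −0.19 without cKO 3 and −1.33 without cKO 1. Nestin cKO 2 had a T-cell list mean of −0.26 log2 CPM, against 1.36 to 3.27 in the other EAE cords, so its cord carried little T-cell signal of EAE. Ecpas lay at 0.13 log2 (SE 0.087, adjusted p = 1), and the 12 fixed genes gave 0 calls.

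**Figure D3:**
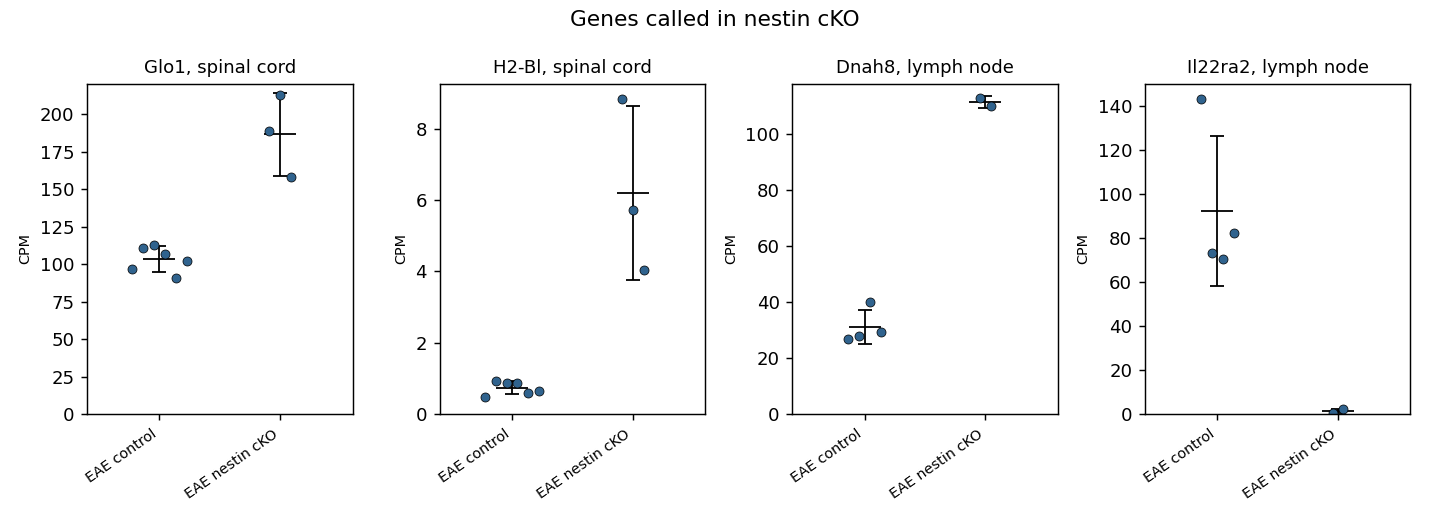
CPM (vertical axes) of Glo1 and H2-Bl in EAE spinal cord and of Dnah8 and Il22ra2 in EAE lymph node, by arm (horizontal axis). Points are libraries and bars are mean ± SD where an arm has more than 1 library. Dnah8 stood at 112 CPM in nestin cKO nodes against 31 in controls and Il22ra2 at 1.48 against 92.1 CPM.

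EAE itself changed 6572 of 18704 genes in cord, 3998 higher and 2574 lower, in 9 libraries (6 controls and 3 cx3cr1 cKO) against 2 without EAE (1 control and 1 cx3cr1 cKO). With control libraries alone the count was 1853. Irf9, a transcription factor of interferon signalling, rose 6.21-fold to 68.1 ± 7.49 CPM (SE 0.22 log2, adjusted p = 2.25e-05). Psmb8 and Psmb9 rose 32.1-fold and 32.7-fold (SE 0.69 and 0.72 log2, adjusted p = 0.000214 and 0.000248), Tap1, the peptide transporter, rose 27.5-fold, and H2-Ab1 rose 86-fold (SE 1.3 log2, adjusted p = 0.00138). Timp1 and Serpina3n, both induced in reactive astrocytes, rose 165-fold and 28.1-fold, and the cycling-cell genes Top2a and Mki67 rose 21.4-fold and 18.3-fold. Ms4a4b of T cells rose at least 175-fold, Sirpb1c of myeloid cells at least 311-fold and the interleukin-18 receptor Il18r1 at least 149-fold, with 0 counts in the cords without EAE. Such floors rest on 3 counts and cover counting error only. Ecpas rose 1.29-fold (SE 0.10 log2, adjusted p = 0.0101), from 113 ± 9.15 to 144 ± 9.68 CPM, but with control libraries alone the adjusted p was 0.0825.

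All 16 T-cell genes rose with EAE in cord, with a list median of 6.52 log2 (adjusted p = 5.71e-13, 0.218 with an estimated correlation). Medians were 5.08 for MHC class II (12 of 12 rose, adjusted p = 4.18e-08, 0.218 with an estimated correlation), 4.63 for interferon-stimulated genes (24 of 24, 1.56e-34, 0.197) and 2.59 for the immunoproteasome (5 of 5, 4.75e-06, 0.199). The 20S core list lay at 0.27 (adjusted p = 0.379). Among falling genes Cnp, a myelin enzyme, fell from 1.47e+03 ± 143 to 920 ± 147 CPM (log2 fold change −0.75, SE 0.16, adjusted p = 0.00218, 0.0628 with control libraries alone) and the synaptic vesicle gene Syp from 910 ± 20.3 to 527 ± 75.3 CPM (−0.81, SE 0.17, 0.00216). Myelin genes had a median of −0.77 (adjusted p = 7.64e-05, 0.341 with an estimated correlation, 12 of 22 fell and 1 rose), and neuronal genes −0.84 (adjusted p = 1.25e-06, 0.277 with an estimated correlation). Hoxb6, a positional gene of the trunk, fell by 1.24 log2 (SE 0.19, adjusted p = 0.000327) and Btbd17 from 25.1 ± 3.45 to 7.34 ± 2.31 CPM. DESeq2 called 7014 genes.

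In EAE lymph nodes of oligodendroglial cKO mice (n = 5 against 4 controls), neutrophil genes lay higher in 12 of 12 members, by a median of 0.75 log2 (adjusted p = 5.96e-09, 0.704 with an estimated correlation). The median was 0.37 without nestin control 2 and 1.61 without the cspg4 control, whose list mean of 6.3 log2 CPM lay above all 5 cKO libraries (5.22 to 6.09). Ngp, a granule protein of maturing neutrophils, stood at 313 ± 89.9 against 131 ± 119 CPM, and Chil3, made by neutrophils and macrophages, at 135 ± 69.1 against 32.5 ± 12.8 CPM (1.98 log2, SE 0.41, adjusted p = 0.797). Complement genes lay higher in 13 of 13 members by 0.3 (adjusted p = 2.6e-06, 0.704 with an estimated correlation), with C1qa by 0.37 log2 (SE 0.18). Regulatory T-cell genes lay higher in 14 of 18 members by 0.22 (adjusted p = 0.00156, 0.704 with an estimated correlation, 0.14 without cspg4 cKO 2), with the costimulator Icos at 175 ± 53.2 against 127 ± 27.2 CPM, and T-cell genes in 15 of 16 by 0.19 (adjusted p = 0.000562, 0.842 with an estimated correlation). The T-cell median was 0.12 without cspg4 cKO 2 or nestin control 2 and 0.31 without cx3cr1 control 1. EdgeR called 0 of 16499 genes (985 at unadjusted p under 0.05, 825 expected by chance) and DESeq2 1. Ecpas lay at 0.11 log2 (SE 0.10, adjusted p = 0.834). Sex is confounded in part with this comparison. The nodes of cspg4 cKO 2 and 3 and pdgfra cKO 1 had the Y-linked gene Ddx3y (115.6 to 143 CPM). Among the controls only control 1 had it (125 CPM), and the remaining cKO and control nodes had 0 CPM.

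In cx3cr1 cKO nodes (n = 3), 18 of 18 cholesterol synthesis genes lay lower, by a median of −0.32 log2 (adjusted p = 5.85e-08, 0.898 with an estimated correlation). Insig1, a sterol sensor, stood at 32.2 ± 2.93 against 43.3 ± 2.36 CPM and the synthase Hmgcs1 at 64.6 ± 2.84 against 86.2 ± 11.6. EdgeR called 0 genes (791 at unadjusted p under 0.05) and DESeq2 5, with Ecpas at −0.02 log2 (SE 0.11, adjusted p = 1, but 0 without cx3cr1 control 1 and 0.04 without cx3cr1 cKO 3). In nestin cKO nodes (n = 2) edgeR called 2 genes, DESeq2 47. Both cKO nodes had counts of the Y-linked gene Ddx3y (110.6 and 125.2 CPM) and almost no Xist. The cspg4, cx3cr1 and nestin controls had Xist (697.9 to 1399 CPM) and 0 CPM of Ddx3y, so sex is confounded in part with this comparison. Dnah8, an axonemal dynein chain, rose 3.62-fold from 31 ± 6.12 to 112 ± 3.15 CPM (SE 0.18 log2, adjusted p = 0.000759). It lies on chromosome 17, where a variant in the mice cannot be told apart from deletion of Ecm29. Il22ra2, the soluble inhibitor of interleukin-22, fell from 92.1 ± 33.6 to 1.48 ± 0.991 CPM (log2 fold change −5.94, SE 0.74, adjusted p = 0.00846), with adjusted p of 0.122 without nestin cKO 1 and 0.08 without the cKO library of column number 3. Against the single nestin-line control the edgeR adjusted p was 0.086 for both genes, at 1.92 and −5.79 log2. The count was 8 without cKO 1, 5 without the library of column number 3 and 4 without nestin control 2. Dendritic-cell genes lay lower there in 11 of 12 members by a median of −0.5 (adjusted p = 0.000231, 0.967 with an estimated correlation), and homeostatic microglia genes in 10 of 11 by −0.73 (adjusted p = 0.000231, 0.932 with an estimated correlation), with Tmem119 at −1.19 (SE 0.27). Lyz1, a lysozyme gene, lay at −2.89 log2 (SE 0.47, adjusted p = 0.0941), and Ecpas at −0.11 (SE 0.13, adjusted p = 0.765, but 0.01 without the library of column number 3).

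Between lymph nodes of 4 EAE controls and of 1 control without EAE, edgeR called 122 genes, 72 higher and 50 lower with EAE, and DESeq2 called 641. With 1 library without EAE, a difference of that animal cannot be separated from EAE, and every p here takes its spread from the other groups. T-cell genes lay lower in 16 of 16 members, by a median of −0.73 log2 (adjusted p = 3.8e-15, 0.127 with an estimated correlation, 13 genes adjusted over the list alone). Cd3e, of the T-cell receptor complex, lay lower with EAE by −1.16 log2 (SE 0.19, adjusted p = 0.0232). Of the B lineage, Ms4a1, which encodes CD20, was 2.42-fold higher (SE 0.25 log2, adjusted p = 0.04) and Jchain, of secreted antibody, 57.7-fold higher (SE 1.2 log2, adjusted p = 0.0433). The Ms4a1 adjusted p was 0.0559 without the cspg4 control and 0.0561 without cx3cr1 control 1, and that of Jchain 0.0543 without cx3cr1 control 1. The Jchain log2 fold change moved from 5.85 to 5.22 without control 1. The cyclin Ccnb1 was 3.75-fold higher (adjusted p = 0.0232), within a proliferation list median of 1.09 (adjusted p = 3.41e-17, 0.127 with an estimated correlation). Haptoglobin, Hp, was 61.4-fold higher, at 40.9 ± 29.3 against 0.66 CPM (adjusted p = 0.0232, 5.94 log2, 5.33 without the cspg4 control), and the chemokine Ccl5 lay at −1.87 log2 (SE 0.28, adjusted p = 0.0171). Ecpas lay at 0.2 log2 (SE 0.17, adjusted p = 0.585). The count was 38 without cx3cr1 control 1 and 61 without the cspg4 control.

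The direct test of whether the oligodendroglial cKO effect differed between cord and node gave 0 edgeR calls of 18905 genes (1054 at unadjusted p under 0.05, 945 expected by chance) and 0 by DESeq2, with 1 call when lymph node cx3cr1 control 1 was left out. The endothelial list as a whole had a lower effect in cord, with a median of −0.73 log2 (adjusted p = 6.95e-08, 0.791 with an estimated correlation, −0.62 and 3.24e-05 with the column-number block as a term). Values short of the threshold were −1.26 for Tek (SE 0.41, adjusted p = 0.866), 1.85 for Mboat2, an acyltransferase of phospholipids (SE 0.38, adjusted p = 0.76), and −0.04 for Ecpas (SE 0.12, −0.08 to 0.04 when each library was left out in turn).

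Brain O4+ cells of oligodendroglial cKO mice (n = 3 against 2 controls) carried more red-cell transcripts and, largely through 1 library, more astrocyte transcripts. Alas2, which makes haem in red-cell precursors, stood at 16.6 ± 2.02 against 7.65 ± 0.0652 CPM (1.12 log2, SE 0.18, adjusted p = 1), and 7 of 7 red-cell genes lay higher by a median of 0.94 (adjusted p = 8.01e-24, 0.323 with an estimated correlation, 6 genes adjusted over the list alone). Astrocyte genes lay higher in 12 of 12 members by 0.68 (adjusted p = 4.56e-10, 0.783 with an estimated correlation, but 0.23 without cspg4 cKO 1), with the folate enzyme Aldh1l1 at 17.1 ± 5.84 against 9.7 ± 0.983 CPM. Neuronal genes lay higher too, by a median of 0.5 (adjusted p = 0.0487, 0.878 with an estimated correlation), and homeostatic microglia genes by 0.23 (adjusted p = 0.0383, 0.878 with an estimated correlation). Without cspg4 cKO 1 these medians were −0.23 and 0.02, and both calls also ended without cspg4 control 1 (medians 0.45 and 0.35) or pdgfra control 1 (0.45 and 0.19), and the neuronal call without cspg4 cKO 2 (0.51). Without pdgfra cKO 1 they were 0.83 and 0.38, and without cspg4 cKO 2 the microglia median was 0.35. The library cspg4 cKO 1 stood apart across cell types, with the highest list means of the 5 for neurons (5.18 log2 CPM, 3.44 to 4.27 in the others) and precursors (6.04, 4.3 to 5.23) and the lowest for mature oligodendrocytes (9.29, 9.71 to 9.88). Ependyma and choroid plexus genes lay lower in 10 of 10 by −0.43 (adjusted p = 6.41e-10, 0.783 with an estimated correlation), with transthyretin, Ttr, at −0.74 log2 (SE 0.23). That median was −0.67 without cspg4 control 1, −0.73 without cspg4 cKO 1 and −0.16 without pdgfra control 1. EdgeR called 0 of 17433 genes (148 at unadjusted p under 0.05, 872 expected by chance) and DESeq2 1. Ecpas lay at 0.13 log2 (SE 0.12, adjusted p = 1). The X-inactivation gene Xist lay higher, and the Y-linked gene Ddx3y lower, in every cKO library than in both controls. The mix of sexes thus cannot be told apart from genotype here.

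In cord O4+ cells (n = 3 against 2) cholesterol synthesis genes lay higher in 17 of 18 members, by a median of 0.18 log2 (adjusted p = 1.78e-05, 0.676 with an estimated correlation), with the farnesyl diphosphate synthase Fdps at 75.4 ± 0.921 against 55.5 ± 5.2 CPM. Homeostatic microglia genes lay higher in 12 of 12 by 0.63 (adjusted p = 1.78e-05, 0.983 with an estimated correlation, 0.35 without cspg4 cKO 2 and 0.41 without pdgfra control 1), with Tmem119 at 6.59 ± 3.35 against 2.71 ± 0.902 CPM. Prr18, an oligodendrocyte-enriched gene, stood at 148 ± 18.2 against 250 ± 18 CPM (−0.75 log2, SE 0.13, adjusted p = 1). Mbp, a main myelin protein gene, lay at −1.18 log2 (SE 0.36, adjusted p = 1, but 0.000531 without the filter on low counts). Mog went the other way, at 482 to 606 CPM in cKO libraries against 448 and 464 in controls. Mature oligodendrocyte list means were 9.67 to 9.92 log2 CPM in cKO libraries and 9.88 and 9.89 in controls. Mitochondrial rRNA took 9.7% to 13.1% in cKO libraries and 16.7% and 19.8% in controls. Xist was higher in every cKO library than in both controls. EdgeR called 0 of 17296 genes (632 at unadjusted p under 0.05, 865 expected by chance), DESeq2 called 18, and edgeR called 17 when cspg4 cKO 2 was left out. Ecpas lay at 0.03 log2 (SE 0.11, adjusted p = 1, −0.04 without pdgfra cKO 1), and the 8 fixed genes tested gave 0 calls in brain and in cord. The test of whether the cKO effect differed between cord and brain O4+ cells gave 0 calls (333 at unadjusted p under 0.05, 920 expected by chance, DESeq2 0). Its red-cell list differed by −1.17 (adjusted p = 9.59e-16, 0.492 with an estimated correlation) and its astrocyte list by −0.84 (adjusted p = 1.06e-07, 0.913 with an estimated correlation), with alpha-globin Hba-a1 at −1.31 (SE 0.39). The astrocyte median was −0.48 without cspg4 control 1 of either tissue, −1.34 without pdgfra control 1 of either tissue and −0.41 without brain cspg4 cKO 1.

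Between 5 cord and 5 brain O4+ libraries 2026 of 18404 genes were called, 1149 higher in cord and 877 lower (DESeq2 2167). Each brain library shares a label number with 1 cord library, and residuals of 4 of these 5 pairs correlated over 0.1. With that number as a block more genes were called. All 23 posterior Hox genes rose, with a median of 5.46 log2 (adjusted p = 2.08e-109, 0.00441 with an estimated correlation). Hoxd8, a positional gene, rose 112-fold to 42.3 ± 5.87 CPM (SE 0.35 log2, adjusted p = 6.34e-06) and Hoxd4 38.2-fold (SE 0.23 log2). All 18 cholesterol synthesis genes rose, by a median of 0.68 (adjusted p = 4.4e-36, 0.0298 with an estimated correlation), with Hmgcs1 up 2.3-fold, from 383 ± 47 to 881 ± 117 CPM (adjusted p = 3.89e-05), and the epoxidase Sqle up 2.03-fold. Immediate early genes rose by a median of 1.47 (adjusted p = 3.59e-44, 0.0298 with an estimated correlation), with Fos up 3.56-fold to 279 ± 92.3 CPM. Klk6, a protease of mature oligodendrocytes, rose 2.46-fold and Hopx 3.5-fold. In the other direction the glutamate transporter Slc17a7 fell by 5.16 log2 (SE 0.38, adjusted p = 4.56e-05) and Ttr from 388 ± 133 to 5.17 ± 4.44 CPM (0.000148). Forebrain genes as a list had a median of −3.12 (adjusted p = 4.59e-16, 0.0867 with an estimated correlation). Ecpas lay at −0.05 log2 (SE 0.063, adjusted p = 0.687).

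The number of genes called between regions depended on single libraries. It was 1140 without brain or cord cspg4 control 1, 1331 without cord cspg4 cKO 1 and 3117 without brain cspg4 cKO 1. Without pdgfra control 1 it was 1309 (brain) and 1302 (cord), and without pdgfra cKO 1 it was 1146 (brain) and 1172 (cord). Every region gene named above kept its call in each of these fits, with Ttr at −6.33 log2 overall and −6.99 and −6.98 without brain or cord pdgfra cKO 1.

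Both brain O4+ libraries of the cx3cr1 line differed in kind from the other 5 brain libraries and entered no comparison. Mog, a myelin surface gene, stood at 11.5 CPM in the cx3cr1 control and 2.55 in the cx3cr1 cKO library, against 492 ± 50.8 in the others. The microglial receptor P2ry12 stood at 821 and 266 CPM against 8.9 ± 3.07, and Tmem119 at 679 and 440 against 3.47 ± 1.3.

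**Figure D4:**
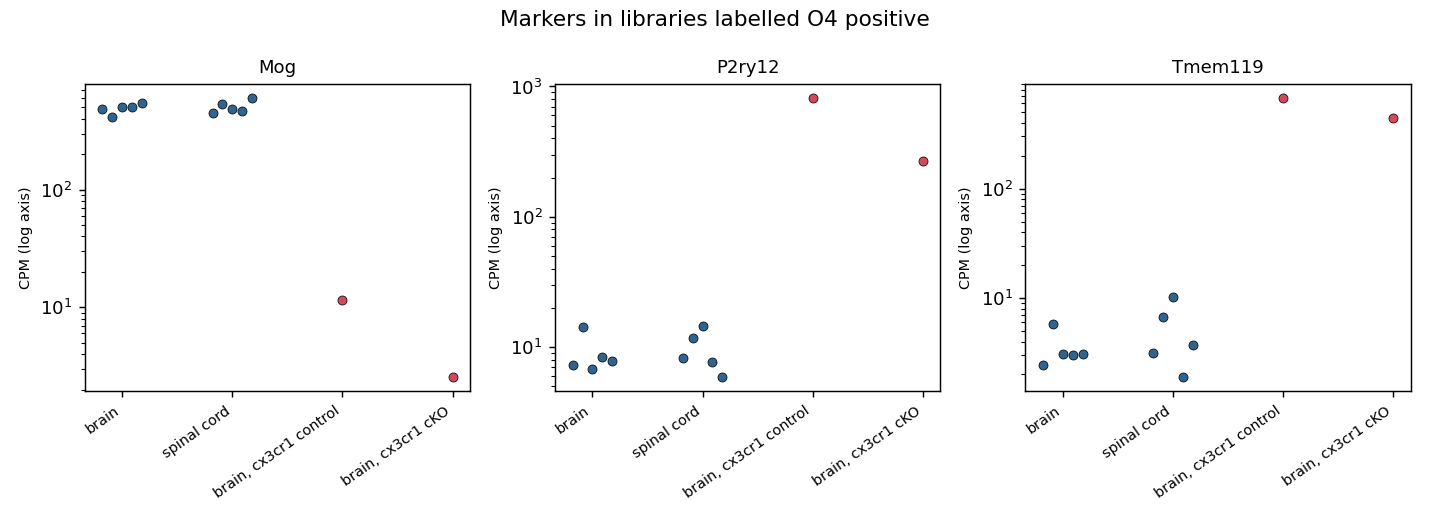
CPM on a log axis (vertical) of the oligodendrocyte gene Mog and the microglia genes P2ry12 and Tmem119 in O4+ libraries, by tissue and line (horizontal axis). Points are libraries. The 2 cx3cr1 line libraries had 11.5 and 2.55 CPM of Mog and 821 and 266 CPM of P2ry12.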

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

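The tests of explanations and of other splits in this part were chosen only after the results were seen, while tests of differences between groups were planned. The prediction for the sum over parent genes was written before that test, but its genes and libraries were picked from the calls.

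Both cx3cr1 line libraries labelled O4 positive carried microglial rather than oligodendrocyte counts, a signal outside the comparisons of the report. Both cx3cr1 totals, 9.03 and 11.2 M (mega) counts, lay below the others (11.9 to 15.9 M). Low depth as a source of counting noise is argued against. The 5 other brain libraries, thinned to the smaller total, kept medians of homeostatic microglia genes of 0.861 to 1.54 times their mean (0.869 to 1.53 unthinned). Thinning keeps the expected share of each gene, so it cannot show other faults of a shallow library. A minor admixture of microglia in oligodendrocytes is argued against too, since mature oligodendrocyte genes had medians of only 2.4% and 0.787% of the other libraries. That most cells were of another kind than O4 positive oligodendrocytes, as after a different sort or a wrong label, could give these values, with medians of homeostatic microglia genes at 95.6 and 48.1 times the others. No biological explanation was tested, because each group is a single library.

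The endothelial list that lay lower in oligodendroglial cKO cords goes with the blocks of column numbers. Sex of the mice is argued against, since the median was still −0.53 log2 with Xist as a covariate. A difference between library batches (block of column numbers) is consistent with the values, because within the high block cKO and control libraries had list means of 3.81 (SD 0.23, n = 5) and 3.76 (SD 0.06, n = 2) with an adjusted p of 0.72. With the block as a covariate the median was −0.29 (adjusted p = 0.000886). Deletion of Ecm29 in oligodendroglia stays open, since the low block holds only 1 such library, from the pdgfra line, at 3.41 against 4.4 (SD 0.29, n = 4) in controls and a median of −1.03.

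Among the genes called in nestin cKO cords, Hmga1b and Atp6v0c-ps2 resemble Hmga1 and Atp6v0c. Reads shared with parent genes could account for this pair, since the summed CPM of the parents changed by −72 in nestin cKO 1 and 2 (266 to 194 CPM, control SD 17.7) where the copies gained 35.5, and cKO 3, without the gain, had 193 CPM of Atp6v0c and 71.7 of Hmga1. The parents lost more than the copies gained, so such sharing leaves a part of their fall without an account. A strain or copy-number variant on chromosome 17 stays open, since 15 of the 49 placed genes among the 50 of smallest p lay there in cord (2.4 expected, exact hypergeometric p = 8.31e-09), and 8 of 49 in lymph node (2.5 expected, exact hypergeometric p = 0.0032). Dnah8 and Glo1 were among 4 such genes in both tissues, with the same sign in 4, and the pair of copies also lay higher in the node of nestin cKO 1 (12.5 and 7.97 CPM) but not in the node of column number 3 (0.422 each), like cord cKO 3. The other comparisons of cKO with controls had only 3 or 4 such genes on chromosome 17 (2.2 to 2.5 expected, exact hypergeometric p = 0.185 to 0.39). If deletion of Ecm29 in nestin cKO libraries were the source, each called gene should stand above every control in all 3 nestin cords. Of the 4 called genes, Glo1 and H2-Bl did. For these 2 deletion stays open, but both lie on chromosome 17, so a variant there in the mice's background cannot be told apart from it. Hmga1b and Atp6v0c-ps2 did not, since nestin cKO 3 had 0.478 and 0.584 CPM, within the controls (0.246 to 0.597 and 0.471 to 1.04). That miss rests on 1 cord library.

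Other splits of the same libraries, with the real grouping included in each tally, were counted to see whether chance can be excluded. It could not for genes at unadjusted p under 0.05 in oligodendroglial cKO cords, with 1826 in the real grouping, up to 2246 in another and 7 of 100 splits reaching the real count. Nor could it for cspg4 (777, up to 3907, 23 of 84 splits), pdgfra (2083, up to 4392, 7 of 84) or cx3cr1 cords (948, up to 5084, 36 of 84). In lymph node it could not for oligodendroglial (985, up to 4054, 27 of 100) or cx3cr1 cKO (791, up to 4714, 17 of 35), nor for the difference between tissues (1054, up to 2393, 20 of 100). For nestin cords the 4 calls were reached by 5 of 84 splits, with up to 4229 calls in another. Splits with up to 2121 calls in cx3cr1, 412 in cspg4, 207 in pdgfra and 425 and 1688 in lymph node comparisons point to a structure of the libraries other than genotype. For the 2026 genes between regions only the real grouping among 100 splits reached the real count, with up to 41 calls in another. Arm means stayed in these fits, so splits that put all libraries of an arm on 1 side had less power, and some splits repeated others. The tally thus does not exclude chance at 1 in 100, though no other split came near the real count. In oligodendroglial against cx3cr1 cKO cords the 1 call was reached by 2 of 84 splits, with up to 1 in another, but these arms nearly coincide with the blocks of column numbers and the edgeR adjusted p was 1 with the block as a covariate, so genotype is not shown as its source. For pdgfra against cspg4 cKO, 10 splits were too few (2 with as many genes).

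Samples far from the others in their group were looked for in 216 values, of which 152 were lists, totals or Ecpas, and 18 were found where chance gives about 1 in 20, or 10.8. In cord, pdgfra cKO 1 had 172 CPM of Ecpas (nearest other oligodendroglial cKO library 147) and pdgfra cKO 3 a dendritic-cell list mean of 2 log2 CPM (nearest 2.7). Among EAE control cords, nestin control 1 had 148 CPM of Clec4e (nearest 59.4), 400 of Cxcl9 (133), 43.6 of F7 (14.8), 129 of Ly6i (29.8) and 31.8 of Ms4a4b (16.2), and control 1 had 4 CPM of Gng8 (2.03), 6.77 of Grin3b (2.89) and 5.69 of Smtnl2 (3.01). In lymph node, nestin control 2 had list means of 4.81 log2 CPM for germinal-centre genes (nearest 4.17) and 5.2 for monocyte genes (5.98), and pdgfra cKO 2 had 5.22 for neutrophil genes (5.91). In brain O4+ cells, cspg4 cKO 1 had list means of −0.961 for cytokine genes (nearest −1.43), 3.3 for homeostatic microglia genes (2.82) and 1.62 for forebrain genes (0.665) and 12.9 CPM of Kcnh3 (5.13), and pdgfra control 1 had 0.0618 CPM of Hoxc8 (0 in the others).

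Differences between groups of effects were tested directly for lists and genes. The oligodendroglial cKO effect differed between cord and lymph node in the cholesterol (−0.38 log2), endothelial (−0.73) and immediate early lists (0.35), with adjusted p of 0.0384, 6.95e-08 and 0.0117 and 0.791 to 0.966 with an estimated correlation. The cKO effect in O4+ cells differed between cord and brain in the MHC class I (0.18), homeostatic microglia (0.38), astrocyte (−0.84), neuronal (−0.73), endothelial (0.35), mural (0.41), ependymal (0.84), posterior Hox (−0.78) and red-cell lists (−1.17), with 0.492 to 0.984 with an estimated correlation. The Hox difference rests on brain counts near the floor, with list means of −2.45 to −1.81 log2 CPM and 2 counts of Hoxd8 in the brain controls. Ependymal genes were low in cord, with list means of 0.75 to 1.89 log2 CPM. Between pdgfra and cspg4 cKO cords the MHC class I (0.34), 20S core (0.14), complement (0.46), disease-associated microglia (0.4), dendritic-cell (−0.42), committed oligodendrocyte (−0.26), cholesterol (−0.26), endothelial (−0.21), proliferation (0.25), stress-response (0.24), immediate early (0.37) and red-cell lists (−1.49) differed, with 0.491 to 0.959 with an estimated correlation. Between oligodendroglial and cx3cr1 cKO cords the interferon-stimulated (−0.55), homeostatic microglia (0.33), cholesterol (−0.44), reactive astrocyte (−0.53), endothelial (−0.81), mural (−0.22), ependymal (0.33), immediate early (−0.13) and red-cell lists (1.24) differed, with 0.277 to 0.979 with an estimated correlation, and the gene LOC118567825 by −3.78. Of these called lists, 1 of 3, 4 of 9, 4 of 12 and 2 of 9 kept the call whichever library was left out.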

How the results depend on the processing

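The tests with blocks of column numbers and without both cspg4 cKO libraries rich in Pdgfra were chosen only after the results were seen. Beyond the counts of calls, 5505 values of named genes and lists kept direction and side of the threshold under the settings fixed beforehand and 373 under those added later, 666 and 34 lost the threshold, 59 gained it and 51 and 8 changed sign. For each change below the cause was not tested, except that fits with fewer libraries have less power.

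RLE factors left every count within 1.5 times its value (6591 for EAE in cord, 117 in lymph node). With DESeq2 the counts were 14 for oligodendroglial, 1 for cspg4, 12 for pdgfra, 5 for cx3cr1 and 13 for nestin cKO cords, 222 for oligodendroglial against cx3cr1 cKO, 1, 5, 47 and 641 for oligodendroglial, cx3cr1, nestin and EAE in lymph node, and 1 and 18 in brain and cord O4+ cells. Without the filter they were 1 for oligodendroglial cKO, 37 for nestin cKO and 328 for EAE in lymph node, 138 in cord O4+ cells, 3192 between regions and 134 for the difference between regions. With the replicate block they were 2 for nestin cords, 0 for oligodendroglial against cx3cr1 cKO, 0 for nestin nodes and 3377 between regions. No paired analysis was possible because no number in the titles links libraries with and without EAE, for the EAE comparisons only. Residuals of cord and node libraries with the same number correlated at 0 to 0.2 (over 0.1 in 4 of 8 pairs, 2 best matches). Those of brain and cord O4+ cells correlated at 0.07 to 0.63 (over 0.1 in 4 of 5 pairs, 4 best matches), a hint of pairs. The labels give each of these O4+ brain libraries a number shared with 1 cord library, but do not say that it marks 1 animal. With only the arms compared, nestin cords gave 1 and oligodendroglial against cx3cr1 cKO 43. With Xist as a covariate the latter gave 0, nestin nodes 6 and EAE nodes 62. Controls of the cspg4 line alone gave 1 for oligodendroglial cKO, own-line controls 1 for cspg4 cords, 0 for nestin cords and 0 for nestin nodes, and control libraries alone 1853 for EAE in cord. With the block of column numbers nestin cords gave 2 and oligodendroglial against cx3cr1 cKO 0, and without both Pdgfra-rich libraries the regions gave 3209.

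Leaving out each library in turn gave 1 to 7 calls in nestin cords, 5710 to 7370 for EAE in cord, 0 to 4 for oligodendroglial against cx3cr1 cKO, 2 to 8 in nestin nodes, 38 to 102 for EAE in nodes, 0 to 1 for cord minus node, 0 to 17 in cord O4+ cells and 1140 to 3117 between regions, and 0 in all other comparisons. A lone library left in an arm was assumed to vary like the other groups. Of the lists called, these held without any 1 library: 24 of 24 for EAE in cord, 16 of 18 between regions, 15 of 18 for EAE in nodes, 5 of 17 in oligodendroglial, 9 of 16 in pdgfra, 2 of 6 in cspg4, 7 of 19 in cx3cr1 and 0 of 9 in nestin cKO cords, 6 of 10 in oligodendroglial, 1 of 7 in cx3cr1 and 2 of 3 in nestin cKO nodes, 5 of 13 in brain and 2 of 7 in cord O4+ cells, 2 of 9 for oligodendroglial against cx3cr1 cKO, 4 of 12 for pdgfra against cspg4 cKO, 1 of 3 for cord minus node and 4 of 9 for the difference between regions.

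Signs changed in oligodendroglial cKO cords for Il17a (main −0.10 log2), at −0.79 to 0.26 over the libraries left out in turn, 0.38 with the replicate block and 0.11 in the high block. Ifng (−0.20) was at −0.53 to 0.37, 0.6 with cspg4 controls, 0.4 with the column block and 0.27 in the high block, Cd4 (0.13) at −0.03 to 0.38, Cd74 (0.31) at −0.01 to 0.88, and Snhg11 (−1.46) at 0.08 with cspg4 controls and 0 in the high block. There the lists of disease-associated microglia, endothelial cells and proliferation were at −0.06, 0 and −0.07 in the high block, and proliferation at −0.05 with cspg4 controls. With each library left out, Ecpas lay at −0.05 to 0.04 in cx3cr1 nodes, −0.26 to 0.01 in nestin nodes, −0.04 to 0.09 in cord O4+ cells and −0.08 to 0.04 in cord minus node. It was at 0 in cx3cr1 nodes with Xist and in cx3cr1 cords with own-line controls, and at 0.09 in cord minus node with the replicate block. In brain O4+ cells Sec14l3 was at −6.57 to 0.78, the committed oligodendrocyte list at −0.23 to 0.06 and the neuron list at −0.23 to 0.83 over the libraries left out, Smco3 at 0.39 with both cx3cr1 libraries, committed oligodendrocytes at 0.3 with the cx3cr1 control and 0.61 with both, and homeostatic microglia at −4.69 and −4.89 with the cx3cr1 control or both. In nestin cords the ranges were −0.81 to 0.11 for disease-associated microglia, −1.07 to 0.26 for monocytes, −0.71 to 0.21 for neutrophils, −0.84 to 0.06 for reactive astrocytes and −0.38 to 0.08 for immediate early genes, with the upper end of each without nestin cKO 2. The replicate block gave −0.64 for red cells in oligodendroglial nodes (−0.11 to 1.74 over the libraries left out), −0.03 for Th1 and Th17 and 0.01 for cytokine genes in cx3cr1 nodes and 0.3 for cholesterol in cord minus node, and Xist gave 0.02 for proliferation in nestin nodes. Own-line controls gave −0.01 for 20S core and 0.08 for endothelial genes in cspg4 cords, and −0.07 for 19S genes, 0.32 for homeostatic microglia and 4.79 for Cx3cr1 in cx3cr1 cords. The column block gave −0.07 for homeostatic microglia in oligodendroglial against cx3cr1 cKO. Results given here without a range kept their sign whichever library was left out.

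Depth and group size limit what can be found in some sets. Of 100 simulated 2-fold changes 25 were recovered for EAE in lymph node, 32 in brain and 52 in cord O4+ cells, so 0 calls in O4+ cells do not exclude changes of that size. In oligodendroglial cKO cords and nodes 84 and 88 were recovered, but the simulated libraries lack structure other than the groups, so 0 calls there do not exclude such changes either.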

Other observations

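All tests in this part were chosen only after the results were seen. Numbers in the column names of the bulk cord libraries fall into a high block (48 to 55, 8 libraries) and a low block (1 to 12, 12 libraries), whose meaning is not given in the sources used here. The high block holds all 3 cspg4 cKO libraries, 2 pdgfra cKO, 2 EAE controls and the control without EAE, and the low block holds every cx3cr1 and nestin library of the cKO arms. Over the 2000 most variable genes the first principal component took 69.9% of the variance, and the second, with 6.87%, put the high block at −21.9 to −8.75 and the low block at −4.1 to 38.8.

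Cx3cr1, the gene into which the cx3cr1 driver is commonly inserted, stood at 102 ± 27.3 CPM (73.6 to 128) in 3 cx3cr1 cKO cords with EAE and 3.64 in the single cx3cr1 control cord, against 269 ± 80.3 CPM (76.5 to 388) in 14 EAE cords of other lines. The ratio of the cx3cr1 line to the other lines was 0.289 (two-sided exact p = 0.00131), while 11 other homeostatic microglia genes had a ratio of 0.793. Disruption of 1 or 2 Cx3cr1 alleles by the driver could give these values, and may add a Cx3cr1 effect to the cx3cr1 cKO comparisons. The cx3cr1 control is also among the pooled EAE controls, so the other comparisons with those controls may carry such an effect too. Its homeostatic microglia list mean in cord, 5.25 log2 CPM, was the lowest of the EAE controls (5.64 to 6.64 in the others). In lymph nodes with EAE the control stood at 1.11 CPM and the cKO libraries at 9.35 ± 1.03, against 20.3 ± 5.16 in 10 of other lines (ratio 0.358, exact p = 0.000999, the smallest possible). In O4+ cells the cx3cr1 control had 72.4 CPM and the cKO 592, and no reason for that difference was tested.

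Across the 18 cords with EAE, the mean log2 CPM of 4 lists was set against that of T-cell genes, with two-sided permutation p adjusted over the 4 relations. Myelin genes had Pearson r = −0.75 (p = 0.00012, adjusted 0.00016, rho −0.81) and neuronal genes r = −0.81 (p = 9e-05, adjusted 0.00016, rho −0.69). Cholesterol genes had r = −0.59 (p = 0.0066, adjusted 0.0066, rho −0.47 with adjusted p 0.051), and MHC class I genes r = 0.91 (p = 1e-05, the smallest possible, adjusted 4e-05, rho 0.74). Without nestin cKO 1 and 2, the farthest from the median, r was −0.68, −0.73, −0.56 and 0.83. Within the high block (n = 7) r was −0.49, −0.22, −0.21 and 0.23, and within the low block (n = 11) −0.83, −0.86, −0.65 and 0.93, so whether a shift in cell shares or a loss per cell lies behind these relations cannot be told apart, because all lists come from the same whole-tissue counts.

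Nestin cKO 2 had a T-cell list mean of −0.26 log2 CPM, where the other EAE cords spanned 1.36 to 3.27 and the cords without EAE had −2.1 and −1.92. Between the single cx3cr1 cKO and control O4+ libraries, not tested because each stands alone, the median log2 differences of the lists ran from −2.66 for neuronal genes to 2.28 for neutrophil genes. All 12 O4+ libraries carried counts of both X-inactivation and Y-linked genes. In brain of the cspg4 and pdgfra lines, Xist stood at 724 to 841 CPM in cKO libraries against 379 and 452 in controls. In cord it stood at 632 to 855 CPM against 451 and 542. The Y-linked gene Ddx3y stood at 36.4 to 54.3 against 70 and 88.7 CPM in brain, and at 39.9 to 62.5 against 59.3 and 85.2 in cord. So the mix of sexes cannot be told apart from genotype in these O4+ comparisons.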
